A study of Homo sapiens with 9 samples.

How the data were processed

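Expression was measured on 9 single-colour Illumina bead arrays, 3 per group, in MHCC97-H, an established human hepatocellular carcinoma cell line. Per the labels' protocols, cells were transfected with shRNA against CD44s (the standard isoform of the cell-surface receptor CD44), against c-Met (the hepatocyte growth factor receptor, gene MET) or with a scrambled sequence, and selected with puromycin or zeocin. The scrambled cells were pooled clones and the c-Met cells single clones, per the labels' protocols, which do not describe the CD44s clones. RNA was cleaned on columns with DNase treatment, and biotinylated cRNA was made with a TotalPrep kit, per the labels' protocols.

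The deposited table holds, per array, an average bead intensity per probe and a detection p-value. GenomeStudio 2011.1 is the tool named, per the submitters' processing notes; further steps are not given in the sources used here. The deposited intensity values were not scaled to a common level, since the mean signal per array ran from 129.5 to 373.1. The deposited detection p-value ranks a probe among negative controls. A second deposited table of processed intensity values was a linear function of the first on each array (largest residual 0.0144), with a background subtracted and each array scaled to a mean of 185.7. Its median intensities, in the order CD44s, scrambled and c-Met, replicates 1 to 3, were 9.76, 8.94, 6.47, 6.64, 6.63, 6.95, 7.22, 8.22 and 6.10. It was used as an alternative only.

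Probes were named through the accession in the file and a RefSeq gene table of GRCh38.p14, used for names alone, since the array's build is not given in the sources used here. Of 47225 probes, 27605 were named by accession, 3390 by symbol and 1388 by synonym, and 14842 kept the file's name. Newer symbols are printed with the file's symbol where they differ. Background was corrected with limma 3.58.1 in R 4.3.3 (normexp estimated from detection p-values, offset 16), 92 spike-in control probes were left out, and arrays were quantile normalized on the log2 scale. Probes with a detection p under 0.05 on at least 3 of 9 arrays were tested, 21164 in all, for 16360 gene names. A gene was represented by its brightest tested probe.

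One limma model with a mean per group was fitted to all 9 arrays, with empirical Bayes moderation and Benjamini-Hochberg adjustment over probes within a comparison, two-sided, at a threshold of 0.05. The comparisons were CD44s against scrambled, c-Met against scrambled, and c-Met against CD44s. A probe below background on every array of a group has only a bound there. Its change is then given as at least N-fold, from the bright group's mean against the higher of each array's lowest detected signal and the probe's own. The comparisons, the model, the gene lists and the rule for named genes were set before the data were examined. The rule took CD44 and MET, the 10 largest changes each way past the threshold with no overlap between groups and a gene symbol other than a provisional one (5 for c-Met against CD44s), up to 4 members with the smallest adjusted p of each list described (3 for c-Met against CD44s), and 5 shared changes each way. Genes placed on the Y chromosome and those of X inactivation were left out.

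Of the gene lists, 37 had at least 5 tested genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera's estimated correlation and with fry. Unlike camera, fry does not set a list against the other genes. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

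The model was tested on simulated data made from the means of the 21164 real probes, with 100 probes changed by 1 and 100 by 2 on the log2 scale. With 1 spread for all groups, the fit for CD44s against scrambled recovered 42 and 90 of them, with 12 false among 144 calls. For c-Met against scrambled it recovered 61 and 93, with 6 false among 160, and for c-Met against CD44s 53 and 87, with 3 false among 143. With each group's own spread, false calls were 85 of 234 for CD44s against scrambled, 4 of 143 for c-Met against scrambled and 129 of 270 for c-Met against CD44s. The CD44s arrays varied more than the others (root mean square SD 0.461, against 0.167 for scrambled and 0.204 for c-Met), and a shared spread understates their error. The planned fit was kept as the reported one. In the same simulations, a fit of only the groups compared gave 18 false of 122, 15 of 189 and 22 of 119 calls. A fit with 1 weight per group, added after these simulations were seen, gave 37 of 165, 38 of 219 and 55 of 179. No fit held false calls near the nominal level for the CD44s comparisons.

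Alternatives tried were the background correction and offset, median scaling, the probe filters, the deposited processed values, an intensity trend, array weights, slide as a fixed or random block, fits within a slide, the replicate number as a block, only the groups compared, the mean of a gene's probes, a fold threshold and leaving out each array. Added after seeing the data were leaving out both dim CD44s arrays, leaving out the 3 dimmest knockdown arrays, array brightness as a covariate and array weights by group. To judge shared changes, all 3 groups were simulated 100 times without change, both knockdowns against the same simulated scrambled arrays, and fitted as planned, with slide as a block and within slide 2. The simulated values hold no slide effect. The arrays lay on 3 slides: slide 1 held 1 CD44s and 2 scrambled arrays, slide 2 held 2 CD44s, 1 scrambled and 2 c-Met arrays, and slide 3 held 1 c-Met array. Below, slide as a block means a fixed block unless called random. Its difference between slides 1 and 2 comes from the scrambled and CD44s arrays. Values for c-Met against scrambled under it thus also depend on CD44s replicate 1. Figures were drawn with matplotlib 3.10.9.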

Results

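Gene expression was profiled in MHCC97-H hepatocellular carcinoma cells carrying CD44s shRNA, c-Met shRNA or scrambled shRNA, with 3 arrays per group, to ask how lowering CD44s or c-Met affects mesenchymal or stemness markers. Mean signal per array was 129.5, 194.7 and 357.7 for CD44s replicates 1 to 3, 248.1, 210.8 and 354.0 for scrambled, and 303.0, 224.0 and 373.1 for c-Met. The share of probes detected was 31.53%, 36.04% and 43.57% in the CD44s arrays, 38.8% to 44.7% in the scrambled arrays and 39.2% to 44.2% in the c-Met arrays. CD44s replicates 1 and 2 were thus the dimmest arrays, and on the first principal component (62.1% of variance) the CD44s arrays lay at -107.4, -41.9 and -10.7, against 20.9 to 25.7 for scrambled and 24.1 to 34.1 for c-Met.

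CD44 signal was lower in the CD44s shRNA arrays and MET signal was not lower in the arrays labelled c-Met shRNA. The brightest CD44 probe had a normalized log2 intensity of 9.76 ± 0.39 (SD, n = 3) in the CD44s arrays and 11.12 ± 0.07 (SD, n = 3) in the scrambled arrays, a log2 change of -1.35 (SE 0.20, limma adjusted p = 0.00243), or 39.1% of the scrambled level. Another CD44 probe changed by -1.77 (SE 0.19, limma adjusted p = 0.000446), and the dimmest by -0.52 (SE 0.24, limma adjusted p = 0.15). With slide as a block the change of the brightest probe was -1.46, within slide 1 (1 CD44s and 2 scrambled arrays) -1.65, and within slide 2 (2 CD44s, 1 scrambled and 2 c-Met arrays) -1.26 with an adjusted p of 0.109. Fits within a slide against scrambled thus rest on 1 array in a group and are given as values rather than as independent support. In the arrays labelled c-Met shRNA, the CD44 difference was -0.27 (SE 0.20, limma adjusted p = 0.77), -0.55 with slide as a block and -0.42 within slide 2. MET, measured by 1 probe, was at 12.59 ± 0.25 (SD, n = 3) there and 12.43 ± 0.06 (SD, n = 3) in scrambled, a difference of 0.16 (SE 0.19, 95% confidence interval -0.27 to 0.59, limma adjusted p = 0.91). It was 0.14 with slide as a block and 0.36 within slide 2. In the CD44s arrays the MET difference was -0.12 (SE 0.19, limma adjusted p = 0.71), -0.20 with slide as a block, 0.13 within slide 2 and -0.52 on the 1 CD44s array of slide 1, the dimmest; without that array it was 0.071. Where the probe lies relative to the shRNA target is not given in the sources used here. Every direction below for c-Met rests on the array labels and not on a measured fall of MET. The c-Met cells were single clones and the scrambled cells pooled clones. An effect of the c-Met shRNA thus cannot be told apart from a difference of clones.

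**Figure D1:**
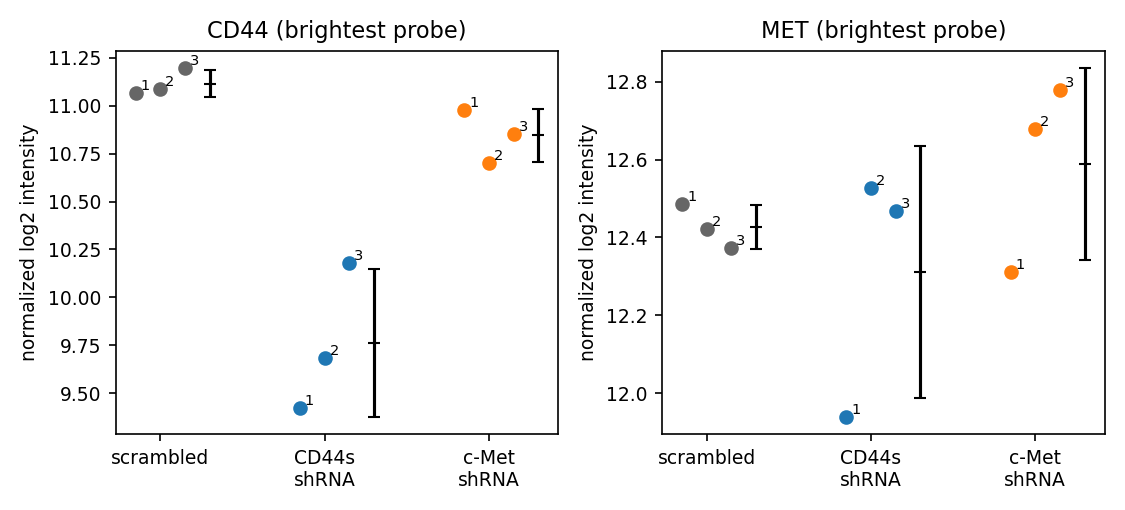
Normalized log2 intensity of the brightest CD44 probe (left) and the MET probe (right) per array, numbered by replicate, with the group mean and SD (n = 3) as bars; the axes do not start at 0. CD44 is lower on all 3 CD44s arrays than on all scrambled arrays, and MET overlaps between scrambled and c-Met arrays.

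In the CD44s shRNA arrays, 10 of 18 hepatocyte and 11 of 21 hypoxia-responsive genes were lower, and 10 of 11 SPANX cancer-testis probes and 7 of 13 replication-dependent histone genes were higher. With an estimated correlation none of the 3 lists passed (adjusted p = 0.0998 each), and housekeeping genes moved by a mean of -0.47. TF, the plasma iron carrier transferrin, changed by -4.90 (SE 0.38), albumin (ALB) by -2.89 (SE 0.24) and FOXA1, a liver transcription factor, by -3.86 (SE 0.39) (n = 3 arrays per group). IGFBP5, an insulin-like growth factor binding protein, fell below background, at least 41.6-fold (limma adjusted p = 1.85e-08). CEACAM5, UGT1A1, COXFA4L2 (NDUFA4L2 in the file), TSPAN8, VSIG1, ITM2A and ITIH2 were the other largest decreases, at -4.36, -4.21, -3.65, -3.57, -3.35, -3.28 and -3.27. Among the increases, the actin-binding genes FLNC and TAGLN changed by 2.79 (SE 0.18) and 2.75 (SE 0.52; 1 of 3 TAGLN probes passed, the lowest at 0.19), SCG5 by 2.68 (SE 0.34) and EPHB6 by 2.61 (SE 0.27). KRT17, below background in scrambled, was at least 6.49-fold higher, with an adjusted p of 0.0126 that rose to 0.0557 at most under alternatives. SPANXE, SPANXD (SPANXE in the file), SPANXC, SPANXB1 and SPANXA1 (SPANXA2 in the file) changed by 3.55, 3.30, 3.21, 3.20 and 3.07. The SPANX genes and UGT1A1 belong to families of near-identical copies, so their probes may not tell members apart. Apart from KRT17, these 20 genes also passed in a fit of only the groups compared, and all 20 passed with slide as a block.

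Of the 18 hepatocyte genes tested, 10 were lower and 0 higher in the CD44s arrays (12 lower and 1 higher adjusted over the list alone). Their mean log2 change was -1.14 (camera adjusted p = 6.98e-07; adjusted p = 0.0998 with an estimated correlation). With slide as a block it was -1.14, within slide 1 -1.20 and within slide 2 -1.07. SERPINA1 changed by -1.83 (SE 0.13) and FGB, a fibrinogen chain, by -2.35 (SE 0.18). Of 21 hypoxia genes, 11 were lower and 0 higher (15 and 0 adjusted over the list alone), with a mean of -0.98 (camera adjusted p = 6.98e-07; adjusted p = 0.0998 with an estimated correlation). It was -1.05 with slide as a block, -1.22 within slide 1 and -0.88 within slide 2. CA9, a carbonic anhydrase, and SLC2A3, a glucose transporter, fell below background, at least 5.39-fold and 3.72-fold. ANGPTL4 changed by -2.47 (SE 0.14) and NDRG1 by -1.76 (SE 0.18). Of 30 oxidative phosphorylation genes, 7 were lower and 0 higher (17 and 0 adjusted over the list alone), among them NDUFB5 at -0.77 (SE 0.15) and COX5A at -0.66 (SE 0.14), whose adjusted p-values within slide 2 were above the threshold. Their mean was -0.44 (camera adjusted p = 7.31e-06; adjusted p = 0.40 with an estimated correlation), and -0.26 with only the bright CD44s replicate 3. It was -0.51 with slide as a block, -0.73 within slide 1 and -0.29 within slide 2. Housekeeping genes, which may reflect array or RNA quality, moved with these groups, 3 of 15 lower and 0 higher (4 and 0 adjusted over the list alone). Their mean was -0.47 (camera adjusted p = 0.00253, and 0.34 with an estimated correlation), -0.52 with slide as a block, -0.72 within slide 1 and -0.33 within slide 2. The list shares GAPDH and PGK1 with glycolysis, SDHA with oxidative phosphorylation and RPLP0 with the ribosomal list, so it is not independent of those lists.

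Of 13 replication-dependent histone genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone), with a mean of 0.70 (camera adjusted p = 1.71e-05; adjusted p = 0.0998 with an estimated correlation). H2BC12 (HIST1H2BK in the file) changed by 2.01 (SE 0.17), H1-2 (HIST1H1C) by 1.72 (SE 0.16) and H4C8 (HIST1H4H) by -2.05 (SE 0.21). The list's mean was 0.73 with slide as a block, 0.71 within slide 1 and 0.75 within slide 2. Of 24 cholesterol synthesis genes, 6 were higher and 1 lower (7 and 1 adjusted over the list alone), led by HMGCS1 at 1.46 (SE 0.21), with a mean of 0.41 (camera adjusted p = 0.000945; adjusted p = 0.0998 with an estimated correlation). That mean was 0.41 with slide as a block, 0.42 within slide 1 (camera adjusted p = 0.086) and 0.40 within slide 2, where HMGCS1 had an adjusted p of 0.059. Median scaling also ended the call of the list.

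Of the 12 mesenchymal markers tested, 5 were higher and 1 lower in the CD44s arrays (6 and 2 adjusted over the list alone). Their mean was 0.62 (camera adjusted p = 0.0266; adjusted p = 0.21 with an estimated correlation), 0.65 with slide as a block, 0.79 within slide 1 (camera adjusted p = 0.0894) and 0.51 within slide 2. Median scaling, array weights and a stricter probe filter also ended the call by camera. By fry the mesenchymal list passed as higher (fry adjusted p = 0.000302). GNG11 changed by 2.24 (SE 0.21), AXL, a receptor tyrosine kinase, by 1.99 (SE 0.19), and FN1, fibronectin, by -1.64 (SE 0.37; 2 of 3 probes passed) with an adjusted p of 0.0184, which rose to 0.0823 at most under alternatives. The stemness markers did not pass as a list by camera (2 of 17 higher and 6 lower, or 4 and 9 adjusted over the list alone, mean -0.55, camera adjusted p = 0.0581). They passed by fry, as lower (fry adjusted p = 0.0031). The mean was -0.61 with slide as a block (camera adjusted p = 0.0657), -0.74 within slide 1 (camera adjusted p = 0.19) and -0.47 within slide 2 (camera adjusted p = 0.0212, against 1 scrambled array); with an estimated correlation the adjusted p was 0.33. SOX9, a transcription factor of progenitor cells, changed by -2.19 (SE 0.17), SOX2, a pluripotency factor, by -1.18 (SE 0.17) and ANPEP, an aminopeptidase, by 2.01 (SE 0.19); within slide 2 SOX2 had an adjusted p of 0.12. Epithelial markers went both ways, 2 of 19 higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.87), with KRT7 at 2.19 (SE 0.22) and CLDN7 at -1.75 (SE 0.30, adjusted p = 0.0758 within slide 2). Their mean was -0.09, and -0.18 with slide as a block, -0.52 within slide 1 and 0.15 within slide 2. Glycolysis genes were lower in 5 of 18, with 0 higher (6 and 0 adjusted over the list alone, mean -0.34, camera adjusted p = 0.0125; adjusted p = 0.22 with an estimated correlation). That mean was -0.34 with slide as a block, -0.41 within slide 1 (camera adjusted p = 0.0894) and -0.28 within slide 2.

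For CD44s against scrambled, limma called 2394 of 16360 genes, 1106 higher and 1288 lower, of which 528 and 441 changed at least 2-fold. In 2390 of them the 3 arrays of both groups did not overlap, as in 36.1% of all genes tested, where chance gives 10%. By fry 23 of 37 lists passed. By camera 17 of 37 lists passed, 6 higher and 11 lower, and 0 passed with an estimated correlation (6 at an unadjusted p under 0.05). All 17 passed with slide as a block, 10 within slide 1 and 14 within slide 2. The gene count is uncertain: with each group's own spread, 85 of 234 calls were false in simulated data, and 782 genes passed in a fit of only the groups compared. With slide as a block 3080 genes passed, within slide 1 8974 and within slide 2 122, of which 121 were among the 2394. Higher genes were 46.2% of calls, 34.7% in the authors' processed values, 53.7% with median scaling and 55.0% with a stricter probe filter, so which direction prevails is not settled.

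**Figure D2:**
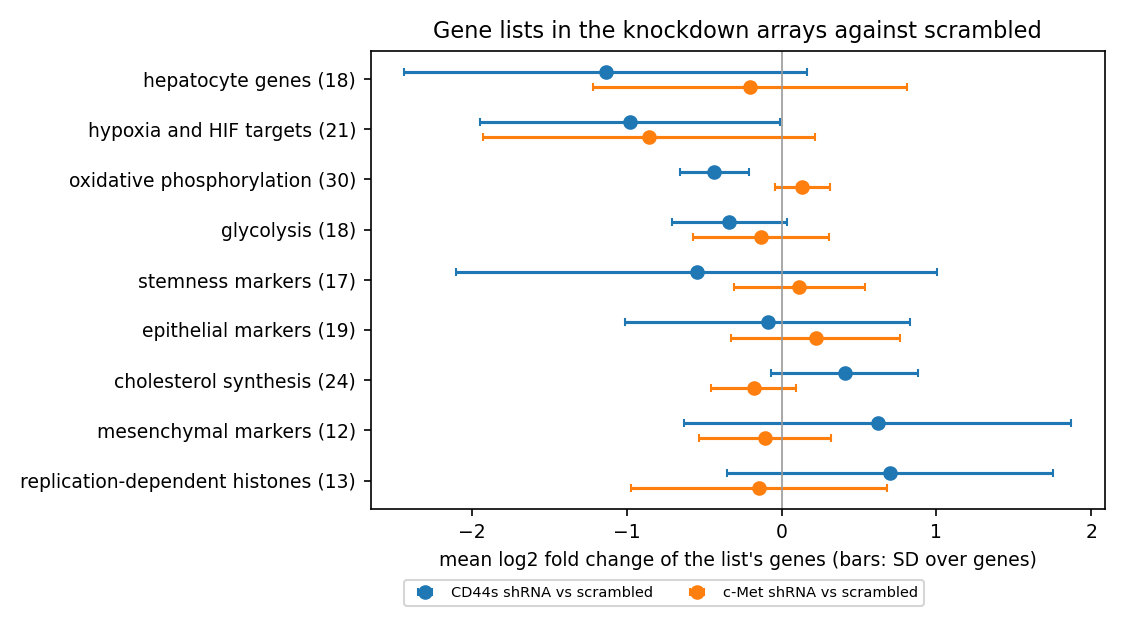
Mean log2 fold change of the tested genes of 9 lists (number of genes in parentheses) in each knockdown against scrambled; bars are the SD over genes and not an error of the mean. The hypoxia list lies at -0.98 in the CD44s arrays and -0.86 in the arrays labelled c-Met shRNA, while the hepatocyte list lies at -1.14 and -0.20, the latter with a median of 0.16.

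In the arrays labelled c-Met shRNA, 7 of 21 hypoxia-responsive genes were lower (adjusted p = 0.063 for the list with an estimated correlation), IGFBP5 was lower, and TM4SF4 and FOSB were the genes with the largest increases. ANGPTL4, a secreted regulator of lipoprotein lipase, changed by -3.91 (SE 0.14), CA9 by -2.70 (SE 0.15) and NDRG1 by -2.17 (SE 0.18), and SLC2A3 fell below background, at least 4.31-fold. IGFBP5 changed by -5.54 (SE 0.16, limma adjusted p = 3.36e-08). TM4SF4 changed by 3.61 (SE 0.48) and FOSB, an immediate-early transcription factor, by 3.33 (SE 0.20); with slide as a block TM4SF4 was at 2.93 with an adjusted p of 0.0789. LGALS2, GLDC, ZNF22, KNG1, SRFBP1, APOE and ASL changed by 2.28, 1.94, 1.92, 1.75, 1.69, 1.64 and 1.61, and SPX (C12ORF39 in the file) was at least 2.83-fold higher. TF, H4C8 and ADORA2B changed by -2.82, -2.78 and -2.63. COXFA4L2, NELL1 and SNHG15 (C7ORF40) fell below background, at least 12.4-fold, 5.68-fold and 5.38-fold. With slide as a block 16 of these 20 genes passed, without APOE, GLDC, SRFBP1 and TM4SF4, and with slide as a random block all 20. Within slide 2 18 passed, without APOE and ZNF22.

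Of 21 hypoxia genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with a mean of -0.86 (camera adjusted p = 1.64e-14; adjusted p = 0.063 with an estimated correlation). The mean was -0.996 with slide as a block and -0.88 within slide 2. Among 18 hepatocyte genes 4 were lower and 0 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.79), and the list had a mean of -0.20 and a median of 0.16. The lower genes were TF and the fibrinogen chains FGB, FGA (3 of 4 probes passed) and FGG at -2.16, -1.60 and -0.93; FGA and FGG did not pass with slide as a block or within slide 2. None of the 12 mesenchymal markers passed by limma (1 higher and 2 lower adjusted over the list alone, and likewise at an unadjusted p under 0.05; camera adjusted p = 0.40). Their mean was -0.11, -0.07 with slide as a block and -0.17 within slide 2, with GNG11 at 0.88 (SE 0.21, limma adjusted p = 0.0789). Of 17 stemness markers 1 passed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.36), ANPEP at 1.12 (SE 0.19, limma adjusted p = 0.0162), and its adjusted p reached 0.27 under alternatives, including slide as a block. The stemness mean was 0.12, -0.02 with slide as a block and 0.07 within slide 2. Of 19 epithelial markers 0 passed by limma (4 higher and 1 lower adjusted over the list alone, 5 and 2 at an unadjusted p under 0.05; camera adjusted p = 0.25), with a mean of 0.22, 0.002 with slide as a block and 0.22 within slide 2. These marker counts rest on a spread shared with the variable CD44s arrays, so markers that did not pass are not shown to be unchanged. In simulated data with each group's own spread, the planned fit recovered 42 of 100 changes of 1 for c-Met against scrambled. A fit of only the groups compared recovered 75, with 15 of 189 calls false against 4 of 143. By camera 6 of 37 lists passed, 3 higher and 3 lower, against 4 by fry. With an estimated correlation 0 passed (5 at an unadjusted p under 0.05). Besides hypoxia, the 5 lists that passed by camera had few members past the threshold. NF-kB and inflammatory cytokines had a mean of 0.28 with 0 of 20 higher and 1 lower, and oncofetal liver genes 0.28 with 2 of 11 higher and 1 lower (5 and 1, and 3 and 1, adjusted over the list alone). Cholesterol synthesis (24 genes), integrins (15) and oxidative phosphorylation (30) had means of -0.18, -0.19 and 0.13 with 0 higher and 0 lower (1 higher, of oxidative phosphorylation, adjusted over the list alone). In the order inflammatory cytokines, cholesterol synthesis, oncofetal liver genes, oxidative phosphorylation and integrins, camera gave adjusted p-values of 0.0346, 0.0363, 0.0398, 0.0489 and 0.0489. Their adjusted p-values with an estimated correlation were 0.28, 0.28, 0.28, 0.84 and 0.28. With slide as a block only the hypoxia list passed, and these 5 means were 0.22, -0.17, 0.30, -0.03 and -0.22; within slide 2 they were 0.27, -0.17, 0.30, 0.11 and -0.30.

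For c-Met against scrambled, limma called 245 of 16360 genes, 123 higher and 122 lower, of which 68 and 82 changed at least 2-fold. In all 245 the 3 arrays of both groups did not overlap, as in 30.2% of all genes tested. With slide as a block 50 genes passed (12 higher and 38 lower), each among the 245, and within slide 2 34 (8 and 26), of which 31 were among them, so the even split is not settled, while 1579 passed in a fit of only the groups compared, which leaves out the variable CD44s arrays. Slide 1 held no c-Met array and slide 3 held 1 c-Met array alone, which drops out of the comparison with slide as a fixed block. With slide as a random block (correlation within slide 0.028) 243 genes passed, 121 higher and 122 lower. The fixed-block fit also took the difference between slides 1 and 2 from the scrambled and CD44s arrays. The 1 CD44s array on slide 1 was the dimmest. The lower count with a fixed block may thus come from the lost array and the dim CD44s array as well as from slides.

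Set directly against each other, the arrays labelled c-Met shRNA had 8 of 18 hepatocyte and 16 of 30 oxidative phosphorylation genes higher than the CD44s arrays, and 10 of 11 SPANX probes and 7 of 13 histone genes lower. Mesenchymal markers went both ways, with 5 of 12 lower and 2 higher, and none of the lists passed with an estimated correlation. TM4SF4, TSPAN8 and FOSB were higher by 4.91 (SE 0.48), 4.87 (SE 0.33) and 3.92 (SE 0.20), and ADH1A and ADH1C, alcohol dehydrogenases of near-identical sequence, by 3.88 and 3.82. SPANXE, SPANXB1, SPANXA1, SPANXD and SPANXC were at -5.04, -4.84, -4.79, -4.21 and -3.48. Hepatocyte genes were higher in 8 of 18 and lower in 0 (11 and 0 adjusted over the list alone; mean 0.93, camera adjusted p = 1.79e-05; adjusted p = 0.0821 with an estimated correlation), with ALB at 3.62 (SE 0.24). Mesenchymal markers were lower in 5 of 12 and higher in 2 (8 and 2 adjusted over the list alone; mean -0.73, camera adjusted p = 0.00908; adjusted p = 0.13 with an estimated correlation), with AXL at -2.16 (SE 0.19). Oxidative phosphorylation genes were higher in 16 of 30 and lower in 0 (20 and 0 adjusted over the list alone; mean 0.57, camera adjusted p = 6.49e-07; adjusted p = 0.40 with an estimated correlation). Housekeeping genes, which may reflect array or RNA quality and share SDHA with the former list, rose by the same mean, 0.57 (6 of 15 higher and 0 lower, 7 and 0 adjusted over the list alone). Their camera adjusted p was 0.000986, and 0.40 with an estimated correlation. Histone genes were lower in 7 of 13 and higher in 0 (8 and 0 adjusted over the list alone; mean -0.85, camera adjusted p = 1.8e-06; adjusted p = 0.0821 with an estimated correlation). For hepatocyte, mesenchymal, oxidative phosphorylation, housekeeping and histone genes in that order, the means were 0.92, -0.68, 0.40, 0.43 and -0.79 within slide 2, and 0.94, -0.72, 0.48, 0.49 and -0.78 with slide as a block. Stemness markers (5 of 17 higher and 3 lower, or 8 and 3 adjusted over the list alone, mean 0.66, camera adjusted p = 0.055; adjusted p = 0.36 with an estimated correlation) passed with slide as a block (mean 0.59, camera adjusted p = 0.0458) and within slide 2 (mean 0.54, camera adjusted p = 0.0307), with SOX9 at 2.55 (SE 0.17). Cholesterol synthesis genes were lower in 11 of 24 and higher in 0 (14 and 1 adjusted over the list alone; mean -0.59, -0.58 with slide as a block and within slide 2; camera adjusted p = 1.79e-05; adjusted p = 0.0683 with an estimated correlation). The hypoxia list did not pass (3 of 21 higher and 3 lower, 4 and 3 adjusted over the list alone, mean 0.12, camera adjusted p = 0.93). By camera 9 of 37 lists passed, 5 higher and 4 lower, also with slide as a block and within slide 2. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05), and by fry 23. Limma called 3544 genes, 1884 higher and 1660 lower, 1112 with slide as a block, 1052 within slide 2 and 1425 in a fit of only the groups compared. In simulated data with each group's own spread, 129 of 270 calls were false. Higher genes were 53.2% of calls, 64.8% in the authors' processed values, 46.0% with a stricter probe filter and 41.9% within slide 2.

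Both knockdowns shared 67 lower and 45 higher genes among 16360, and 22 genes went in opposite directions. Independent lists of the same sizes would share 9.61 and 8.32, with 17.9 opposite, and simulated unchanged groups that share their scrambled arrays shared 0. Those groups hold no real effects and their genes were drawn independently. A count near 0 is thus built in and gives no support. The 112 shared genes were 26 with slide as a block, 13 within slide 2 and 44 to 312 with 1 array left out. The counts treat near-identical copies as separate genes: 13 of the 45 are GAGE genes, and 3 of the 22 are SPANX genes. Both comparisons use the same 3 scrambled arrays, too few to split, so part of the excess may come from them. The shared decreases were led by IGFBP5, COXFA4L2, NELL1, TF and CA9, and the shared increases by GAGE12F, ZNF22, SRFBP1, GAGE12B and GAGE2E. Of the GAGE12F probes 1 of 2 passed in each knockdown. The increases were less firm, since GAGE12F, GAGE12B, GAGE2E and SRFBP1 did not pass in the arrays labelled c-Met shRNA with slide as a block. Across genes, which are not independent replicates, Pearson's r was 0.092 and Spearman's rho 0.0615, against 0.21 and 0.24 in the simulated groups. Pearson's r was 0.51 with slide as a block against a simulated 0.37, and within slide 2 0.26 against 0.34, so whether it lies above or below that of unchanged groups is not settled. The covariance was 0.0164 against a simulated 0.00898.

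**Figure D3:**
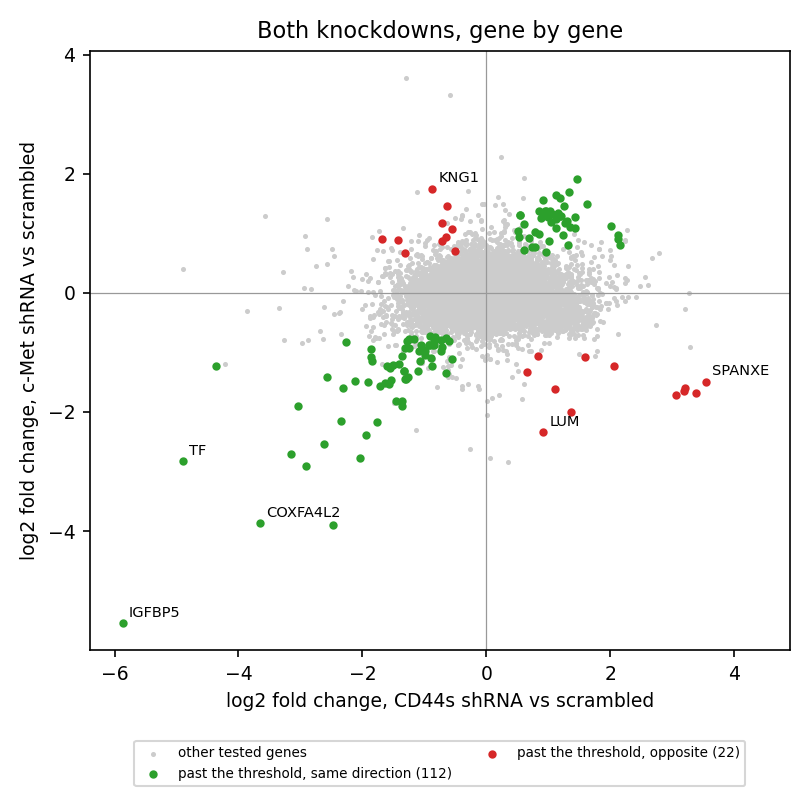
Log2 fold change of each tested gene in CD44s shRNA (horizontal) and c-Met shRNA (vertical) against scrambled, each point a gene; green points passed the threshold the same way in both and red points in opposite directions. IGFBP5 lies at -5.87 and -5.54, and SPANXE at 3.55 and -1.49. IGFBP5 was below background in the CD44s arrays, so its first value is a fitted one and only a bound is known.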

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

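The tests of array brightness, of the MET label and of the shared decreases were chosen only after the results were seen.

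In all, 22 genes were past the threshold in opposite directions in the knockdowns, with the difference between both knockdowns past it too, which is why they are listed here. SPANXA1, SPANXB1 and SPANXE differed by -4.79, -4.84 and -5.04 on the log2 scale (c-Met minus CD44s), and KNG1, a liver-made kininogen, by 2.62. KNG1 was below background in the CD44s arrays, so the difference is at least 3.75-fold. Of 11 SPANX probes, 10 were higher in the CD44s arrays (median 3.21) and 6 lower in the arrays labelled c-Met shRNA (median -1.32), where 1 of 2 SPANXB1 probes passed.

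With the shared spread far more genes were called in the CD44s arrays, 2394 against 245, and 2 of these arrays were the dimmest of all; it stays with array brightness as a covariate (2348 against 422), slide as a block (3080 against 50) and median scaling (1235 against 140), but turns in fits of only the groups compared (782 against 1579) and without both dim arrays (1346 against 1579), and nearly ends with group weights (1680 against 1622). If weak labelling of those arrays made the calls, the bright replicate 3 would show little of the change. Among 5640 genes called without replicate 3, replicate 3 showed a median of 0.36 of the fitted change (quartiles 0.13 and 0.59), with 85.3% moving the same way. Both changes were taken against the same scrambled arrays, and these genes were chosen on replicates 1 and 2. What unchanged arrays would give was not simulated. The share of 0.36 lies between the bounds set for this test, under 0.2 for labelling as the cause and at least 0.5 against it. For these genes weak labelling thus cannot be told apart from an effect of the knockdown or of a clone. Dimmer arrays of other groups moved little along the CD44s change of the 2394 genes. Slopes were 0.075 (r 0.34) for c-Met replicate 2 and 0.012 (r 0.07) for scrambled replicate 2. Both were brighter than CD44s replicates 1 and 2, so these slopes do not settle it. The size of the excess depends on the fit. A spread shared by the groups made many false calls for the CD44s arrays in simulated data. The fit without both dim arrays also shares a spread but keeps only replicate 3 of the CD44s arrays, so its turn may come from the number of arrays. In the planned fit, genes changed at least 2-fold were 528 higher and 441 lower for CD44s, against 68 and 82 for c-Met. Over the 2394 genes the median change in the called direction was 1.155, 0.90 and 0.612 on CD44s replicates 1 to 3. Over all genes the median absolute change was 0.547, 0.354 and 0.217. With only replicate 3 kept, the hypoxia mean was -0.774 against -0.981, and the housekeeping mean -0.244 against -0.466. The histone mean was 0.726 against 0.701, and the cholesterol mean 0.40 against 0.409.

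MET was not lower in the arrays labelled c-Met shRNA. A saturated probe is argued against, since MET reached at most 49.0% of the brightest signal on those arrays. An exchange with the CD44s label is argued against by CD44, which changed by -0.27 (SE 0.20) there and by -1.35 in the CD44s arrays. RNA of the scrambled cultures on these arrays is argued against by 150 genes past the threshold and changed at least 2-fold; the simulated data had 4 false calls over probes, without a fold threshold. A probe outside the part affected, an effect on protein alone, loss of the knockdown and a wrong label from outside the series stay open and untested.

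IGFBP5 was lower in both knockdowns, and so were CA9 and other hypoxia-responsive genes. Chance values of the shared scrambled arrays gave at most 0 shared decreases in 100 simulated sets, against 67 observed. But 3 arrays are too few to split, and the simulation holds no real effects, so few calls in it are built in. The scrambled cells may have been in another state, such as low oxygen, but the mean difference of the hypoxia list between the knockdowns, 0.12 (camera adjusted p = 0.93), does not show that its genes moved alike, since 3 were higher and 3 lower, among them ANGPTL4 at -1.43 (limma adjusted p = 0.000191; 1 of 2 probes passed). Such a state and a shared effect of both knockdowns cannot be told apart with 1 scrambled control. Nor can a difference of clones be told apart from them. The scrambled cells were pooled clones and the c-Met cells single clones, and the CD44s clones are not described. Glycolysis genes, also responsive to oxygen, had a mean of -0.13 in the c-Met arrays, with 0 of 18 lower (camera adjusted p = 0.34). In the CD44s arrays their mean was -0.34, with 5 of 18 lower (camera adjusted p = 0.0125, and 0.22 with an estimated correlation).

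Other splits of the 6 arrays were too few, 10 per comparison, to give a share under 0.05. In each comparison the real split alone, 1 of 10, gave as many genes. The other splits mix both groups, so any difference between the groups, whatever its cause, widens their spread. Few calls in them are thus built in and give no support. For CD44s against scrambled the real split gave 2394 genes by limma and the other splits at most 0 (5460 and 1673 at an unadjusted p under 0.05). For c-Met against scrambled it gave 245 and at most 0 (1708 and 146), and for c-Met against CD44s 3544 and at most 0 (5966 and 2830).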

How the results depend on the processing

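The alternatives with dim arrays left out, with array brightness as a covariate and with array weights by group were chosen after the data were seen. Causes were not tested unless the construction of an alternative shows one. Values under alternatives numbered 8039, for named genes and for the count of genes in opposite directions. Of these, 7094 kept direction and side of the threshold or, for the count, stayed close. Another 928 lost significance, 0 reversed and 17, all of that count, moved. CD44 and MET against scrambled are not included and are given below, with 5 reversals of MET. Over 912 values of gene lists, 788 kept direction and side of the threshold, 123 lost significance and 1 reversed. That was the oxidative phosphorylation list in the c-Met arrays, at -0.033 with slide as a block and 0.114 within slide 2. Where leaving out arrays left 1 array in a group, it was assumed to vary like the others. Precision is limited in CD44s replicates 1 and 2, with 31.53% and 36.04% of probes detected.

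CD44 in the CD44s arrays lost significance within slide 2 (-1.264). MET in the CD44s arrays reversed with array weights (0.079), within slide 2 (0.126), without both dim CD44s arrays (0.041), without the 3 dimmest knockdown arrays (0.041) and without CD44s replicate 1 (0.071), and was -0.515 within slide 1, past the threshold but on 1 CD44s array, the dimmest.

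Against 2394 genes, CD44s against scrambled gave 969 at 2-fold, 1235 with median scaling, 9056 with array weights, 122 within slide 2, 8974 within slide 1, 782 with only the groups compared and 1346 without both dim arrays. Against 245, c-Met against scrambled gave 150 at 2-fold, 140 with median scaling, 156 with the deposited processed values, 2049 with array weights, 50 with slide as a block, 34 within slide 2, 1579 with only the groups compared or without both dim CD44s arrays, 1507 without the 3 dimmest, 422 with brightness as a covariate and 1622 with group weights. The larger counts among fits without CD44s arrays follow from their spread leaving the fit. Against 3544, c-Met against CD44s gave 1362 at 2-fold, 8831 with array weights, 1112 with slide as a block, 1052 within slide 2, 1425 with only the groups compared, 2322 without both dim arrays and 2346 with group weights.

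Against 17 lists, CD44s gave 11 with array weights; against 6, c-Met gave 2 with a stricter probe filter, with the processed values or with slide as a random block, 1 with slide as a fixed block and 3 without the 3 dimmest arrays; against 9, c-Met against CD44s gave 16 with median scaling, 17 with no filter and 14 with group weights. Each gave 0 with an estimated correlation.

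The correlation of 0.092 was 0.011 with a stricter filter, 0.509 with slide as a block, 0.262 within slide 2, 0.206 without both dim arrays, 0.2 without the 3 dimmest and 0.213 with brightness. The 112 shared genes were 60 with median scaling, 71 with the processed values, 764 with array weights, 26 with slide as a block, 13 within slide 2, 299 without both dim arrays, 331 without the 3 dimmest, 177 with brightness and 272 with group weights.

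Leaving out 1 array gave CD44 changes of -1.563 to -1.184 in the CD44s and -0.339 to -0.2 in the c-Met arrays, and MET changes of -0.223 to 0.071 and 0.068 to 0.302. The lists past the threshold were 15 to 18, 3 to 8 and 9 to 12 in the order CD44s, c-Met and c-Met against CD44s. Genes were 588 to 5640 for CD44s: 5640 without CD44s replicate 3, 1470 without CD44s replicate 2, 588, 777 and 758 without scrambled replicates 1 to 3, and 1590 and 1584 without c-Met replicates 1 and 3. They were 93 to 1002 for c-Met: 1002 and 378 without CD44s replicates 1 and 3, 93, 111 and 93 without scrambled replicates 1 to 3, and 98, 111 and 123 without c-Met replicates 1 to 3. They were 1505 to 6148 for c-Met against CD44s: 6148 without CD44s replicate 3, and 1505, 2015 and 1625 without c-Met replicates 1 to 3. The correlation was 0.022 to 0.168 and the shared genes 44 to 312.

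The replicate numbers were not taken as pairs. The array titles hold no such numbers, so these correlations cannot test a pairing in the experiment. Same-numbered deviations correlated at -0.128, 0.01 and -0.034 between CD44s and scrambled arrays, and at 0.096, 0.074 and -0.031 between c-Met and scrambled arrays. Between CD44s and c-Met arrays they correlated at -0.062, 0.143 and 0.306, and differently numbered ones at -0.362 to 0.193. With the replicate number as a block, 2025, 175 and 3211 genes passed, 1933, 173 and 3118 of them kept from 2394, 245 and 3544. Another scaling moved the median of all genes: in the CD44s arrays from -0.029 to 0.138 with median scaling and -0.159 with the processed values, and in c-Met against CD44s from 0.044 to -0.13 and 0.169.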

Other observations

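The fit without both dim CD44s arrays was chosen after the data were seen, and the copy-number test before its result. Genes named here outside the naming rule were picked after their values were seen.

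Further lists passed camera's threshold in the CD44s arrays. Housekeeping genes had a mean of -0.47 there, a larger decrease than that of every lower list below but complement and coagulation. NRF2 and glutathione genes were lower in 6 of 25 and higher in 0 (7 and 0 adjusted over the list alone; mean -0.32, camera adjusted p = 0.0153; adjusted p = 0.41 with an estimated correlation), with AKR1C3 at -0.92 (SE 0.15) and GPX2, a glutathione peroxidase, at -1.13 (SE 0.18). TGF-beta target genes were lower in 6 of 15 and higher in 0 (8 and 1 adjusted over the list alone; mean -0.45, camera adjusted p = 0.0278; adjusted p = 0.41 with an estimated correlation), with ID3 at -1.14 (SE 0.16) and CCN2 at -1.25 (SE 0.18). Complement and coagulation genes were lower in 4 of 18 and higher in 1 (5 and 1 adjusted over the list alone; mean -0.56, camera adjusted p = 0.0266; adjusted p = 0.22 with an estimated correlation), with C4BPA at -2.74 (SE 0.22) and PROS1 at 1.04 (SE 0.15). YAP target genes were higher in 5 of 16 and lower in 3 (10 and 3 adjusted over the list alone; mean 0.49, camera adjusted p = 0.0266; adjusted p = 0.33 with an estimated correlation), with F3, tissue factor, at 1.05 (SE 0.15) and CCN2 lower. In that order, the means were -0.37, -0.51, -0.63 and 0.57 with slide as a block, -0.51, -0.67, -0.70 and 0.80 within slide 1, and -0.22, -0.35, -0.55 and 0.34 within slide 2. The YAP call ended without CD44s replicate 3 and with array weights. Without CD44s replicate 2 the TGF-beta and complement calls ended. So did the TGF-beta call with the mean of a gene's probes, and the complement call with no filter or a stricter probe filter. Within slide 1 the TGF-beta and complement lists did not pass (camera adjusted p = 0.0894 and 0.19), and without both dim CD44s arrays, which leaves 1 array, neither the NRF2 nor the TGF-beta list passed (means -0.16 and -0.23, camera adjusted p = 0.0671 for both). Oncofetal liver genes (4 of 11 higher and 0 lower, mean 0.54; adjusted p = 0.21 with an estimated correlation) and NF-kB and inflammatory cytokines (3 of 20 higher and 0 lower, mean 0.36; adjusted p = 0.22 with an estimated correlation) passed by camera but not within slide 1 (camera adjusted p = 0.24 and 0.34). Genes of G2/M and mitosis (5 of 30 lower and 0 higher, mean -0.27; adjusted p = 0.58 with an estimated correlation), of the unfolded protein response (7 of 25 lower and 2 higher, mean -0.36; adjusted p = 0.40 with an estimated correlation) and of cytosolic ribosomal proteins (3 of 36 lower and 0 higher, mean -0.20; adjusted p = 0.55 with an estimated correlation) passed but not within slide 2 (camera adjusted p = 0.20, 0.0973 and 0.47). Without CD44s replicate 1, the dimmest array, the G2/M and ribosomal lists did not pass either (means -0.13 and -0.10, camera adjusted p = 0.21 for both), and the ribosomal list also did not pass without scrambled replicate 2. In the order given, these 5 lists had means with slide as a block of 0.55, 0.33, -0.35, -0.42 and -0.24. The oncofetal and inflammatory cytokine calls also ended without CD44s replicate 3 and with a stricter probe filter. Median scaling ended the oncofetal call too, and array weights the cytokine call.

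Directly compared, metallothioneins were lower in the arrays labelled c-Met shRNA than in the CD44s arrays in 2 of 5 genes and higher in 0 (4 and 0 adjusted over the list alone; mean -1.09, camera adjusted p = 0.00322; adjusted p = 0.13 with an estimated correlation). MT2A was at -1.54 (SE 0.17) and MT1A at -1.47 (SE 0.22), which are close copies. The mean was -1.18 with slide as a block and -1.28 within slide 2. NRF2 (9 of 25 higher and 0 lower), complement (9 of 18 and 1) and housekeeping genes (6 of 15 and 0) were higher by means of 0.46, 0.80 and 0.57 (11 and 0, 9 and 1, and 7 and 0 adjusted over each list alone; adjusted p = 0.40, 0.18 and 0.40 with an estimated correlation). Those means were 0.40, 0.70 and 0.49 with slide as a block, and 0.35, 0.67 and 0.43 within slide 2.

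Several genes went in opposite directions in the 2 knockdowns. INHBB, a subunit of activin, changed by 1.36 (SE 0.22) in the CD44s arrays and -2.001 (SE 0.22) in the arrays labelled c-Met shRNA, and LUM, the matrix proteoglycan lumican, by 0.92 (SE 0.17) and -2.35 (SE 0.17). The acute-phase genes ORM1 and ORM2 changed by -1.43 and -0.55 in the CD44s arrays and by 0.90 and 1.07 in the others; they are near-identical copies.

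The c-Met cells were single clones, and a clone may carry a copy-number difference of a whole chromosome. In the arrays labelled c-Met shRNA, 0 of 23 chromosomes had a median at least 0.2 from that of all genes. A copy-number difference that shifts a chromosome's genes by less would not meet this bound, so it stays open. The largest median, on chromosome 8, was -0.11 against 0.009 for all genes (resampling adjusted p = 0.000627, from the smallest p that 10000 resamples can give). Relative to all genes of each array, c-Met replicates 1 to 3 had medians of -0.129, -0.131 and -0.116 on chromosome 8. On chromosome 17 they had -0.07, -0.065 and -0.083. Scrambled arrays lay between -0.019 and 0.014 on both, and CD44s arrays at -0.152, -0.105 and -0.049 on chromosome 8. In the c-Met arrays 5 chromosomes passed the threshold. The resampling drew genes at random, and genes are not independent replicates. Its p-values thus do not measure the spread between arrays or clones and may be too small. More passed in the other comparisons, 11 for CD44s against scrambled and 12 for c-Met against CD44s, with the largest medians on chromosome 13, -0.22 against -0.036 for all genes and 0.234 against 0.054. Its median was -0.172, -0.247 and -0.118 on CD44s replicates 1 to 3, and whether a clone or array quality lies behind this was not tested. Smaller segments were not tested.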
